A study of Mus musculus with 44 samples.

How the data were processed

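The series holds ChIP-seq of mouse HPC7 cells in which H3K4me1 (9 libraries), H3K4me2 (9), IgG (2), Snai1 (12) and input DNA (12) were sequenced. Cells were transduced with an MSCV-IRES-GFP retrovirus carrying no insert, wild-type Snai1 or mutant Snai1, and were sorted for GFP and expanded, per the labels' protocols. Snai1 libraries were made with the TruSeq ChIP kit and methylation libraries with a variation of the Illumina protocol at BGI, per the labels' protocols. The deposited counts of H3K4me1, H3K4me2 and IgG reads are raw read counts in windows around transcription start sites, with 1 value per Entrez gene ID, made from Subread alignments with featureCounts per the submitters' processing notes, which give no versions. The name of the table states windows of 5 kb around the start site, and it holds no window coordinates. For Snai1, the deposited peak lists give per peak the fold enrichment over local background, the -log10 q and the summit position, and MACS2 is the peak caller per the submitters' processing notes. Each construct has 1 list although it has 4 technical replicates, so the lists have no replicate check, and no source states whether the input libraries served as control. The builds are GRCm38 and mm10, which name the same assembly, per the submitters' processing notes.

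All 20 columns of the count table were matched to samples by construct, mark and replicate number. The labels number the methylation replicates and do not say whether they are separate transductions or cultures. Of 27095 gene IDs, 25204 (93.0%) were matched to symbols in a RefSeq table of the GRCm38.p6 assembly. Rows with counts equal to those of an earlier row (50) and rows with no read (20) were left out, which left 27044. Windows of neighbouring genes can overlap and share reads, and they cannot be told apart without coordinates, so such neighbours are named where both stood among the named genes. Depth per library is the column total, and precision is set by these counts and by the number of libraries.

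Counts were tested in each mark over all 3 constructs with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), with TMM factors, filterByExpr by group, and Benjamini-Hochberg adjustment over all windows tested, two-sided, at 0.05. CPM of named genes are on the TMM-scaled library size and those of the Snai1 window across marks and IgG on column totals. Where no window changes, an exact test gives an unadjusted p under 0.05 in a share of 0.05 of windows. The difference between marks was tested as the interaction of mark and construct in 1 fit of both marks. For pairs of libraries the variance beyond counting error was measured over windows with at least 20 reads in the pair. Empty-vector H3K4me1 replicates 2 and 3 differed by no more than counting error and were summed to 1 sample in the main tests, a choice made after seeing the data. Gene lists were tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation as an alternative, and with fry, adjusted over the 12 lists in each mark and comparison. The 6 tests of start-site windows of genes near a wild-type Snai1 peak were adjusted together.

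The 12 lists were fixed before the data were examined: epithelial, mesenchymal, stem and progenitor, myeloid, erythroid and megakaryocytic, mast cell and basophil, lymphoid, Lsd1 complex, H3K4 enzymes, interferon and retrovirus response, cell cycle, and housekeeping genes. The text names by rule Snai1, Kdm1a, Gfi1 and Gfi1b, and in each comparison up to 12 windows per direction with the largest log2 fold change among those that passed, whose libraries do not overlap between the groups and whose mean CPM in the higher group is at least 2 times the median of the silent families (olfactory and vomeronasal receptor genes, 1482 windows). Predicted genes were left out of the naming. Where under 10 windows passed, the 10 with the smallest p under the same rule are named as not passing. In each list up to 4 members per direction that passed were named, or else up to 2 with the smallest p. Genes named only in the other observations were chosen after their values were seen. Windows whose groups did not overlap made up 6.9 to 12.9% of H3K4me2 windows, where chance gives 10%, and for H3K4me1 14 and 10.5% against the empty vector (chance 20%) and 8.6% between wild type and mutant (chance 10%). Of the peaks, the 12 with the highest -log10 q in the wild-type and in the mutant list that overlap no empty-vector peak qualified, and up to 4 members of each list near a wild-type peak.

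Peak lists were compared with bedtools 2.31.1 and Python 3.11.15 (pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6), an overlap being at least 1 base. Shares of peaks carry exact Clopper-Pearson 95% intervals. The reference holds gene ends without strand, so a gene was counted as near a peak where the peak lay within 5 kb of either annotated end, in place of a peak inside the start-site window, for 25185 genes with coordinates. Fisher's exact test, two-sided, compared gene lists with the other genes, adjusted over both peak lists. No genome sequence was at hand, so the planned search for E-box motifs at summits was left out. Signal over IgG is the log2 ratio of mean CPM by column totals in windows with a mean IgG count of at least 1. Correlations of changes against the shared empty-vector libraries were set beside 100 simulations of unchanged groups with the same controls and, added after seeing the data, beside 100 that also carried the means of replicate 1 and of replicates 2 and 3. Chromosome shifts are medians over windows with a mean count of at least 30 (20 for IgG).

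The window test was tested on simulated data drawn from the negative binomial with the mean of each window over all libraries of the mark, the fitted dispersions and the library sizes, with changes added to the wild-type libraries and tested against the empty vector. In H3K4me2, over 25742 windows, it recovered 17.9% of windows changed 1.5-fold, 62.7% of those changed 2-fold and 95.5% of those changed 4-fold, with 11 unchanged windows called. In H3K4me1, over 25728 windows, it recovered 0%, 9% and 77.3%, with 5 unchanged windows called.

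Alternatives fixed before the data were examined were RLE factors, column totals or factors from the silent families in place of TMM, no count filter, DESeq2 1.42.0, the replicate number as a block, only the compared groups in the fit, each library left out in turn, other peak thresholds, overlaps and sets, and an estimated correlation in camera. Added after seeing the data were a batch term for replicate 1 against replicates 2 and 3, replicates 2 and 3 alone, these replicates summed with the batch term, all 9 H3K4me1 libraries counted apart, and the gene lists without each library. Figures were drawn with matplotlib 3.10.9.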

Results

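The study measured histone H3 lysine 4 methylation and Snai1 binding in HPC7 cells, a mouse haematopoietic progenitor line grown with stem cell factor. Cells carried a retroviral vector with no insert, with wild-type Snai1, or with a Snai1 mutant whose interaction with the demethylase Lsd1 (gene Kdm1a) is impaired, and GFP-positive cells were sorted and expanded. For each construct there were 3 libraries of H3K4me1 and 3 of H3K4me2, and 2 IgG libraries came from wild-type Snai1 cells. Snai1 ChIP and input DNA had 4 technical replicates each per construct, given as 1 peak list per construct. Counts in windows around transcription start sites summed to between 8694515 and 18199945 per H3K4me2 library, between 4042976 and 8813537 per H3K4me1 library, and to 2714255 and 3355479 in the IgG libraries. The median window held 72 to 143 counts in H3K4me2 libraries and 101 to 201 in H3K4me1 libraries.

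Housekeeping windows stood far above windows of gene families silent in blood cells (olfactory and vomeronasal receptors) in the methylation libraries. The ratio of their median CPM was 27.7 to 61.1 in H3K4me2, 16.3 to 43.7 in H3K4me1, and 1.36 and 2.31 in IgG. In wild-type cells the median log2 ratio of H3K4me2 over IgG was 1.34 for housekeeping windows, 1.31 for genes of H3K4-modifying enzymes and 1.27 for stem and progenitor genes, against -1.71 for lymphoid genes, -2.65 for epithelial genes and -3.79 for the silent families. For H3K4me1 these medians were 0.78, 0.62, 0.71, 0.18, -0.86 and -3.12 in the same order.

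Replicate 1 stood apart from replicates 2 and 3. The ratio of the observed to the counting variance between libraries was 9.49 to 17.7 in the 12 pairs of replicate 1 against replicate 2 or 3 of the same construct and mark. It was 0.980 to 2.30 in the 6 pairs of replicates 2 and 3, and 2.18 to 4.74 in the 6 pairs of different constructs within replicate 1. Empty-vector H3K4me1 replicates 2 and 3 differed by no more than counting error (0.980) and were counted as 1 sample, so that group had n = 2. Within replicates 2 and 3, whole chromosomes stood apart between constructs in both marks. On chromosome 12 the empty-vector median lay at -0.58 in H3K4me2 and -0.46 in H3K4me1 on the log2 scale against the other constructs, on chromosome 8 the mutant lay at 0.37 and 0.45, and on chromosome 17 wild type lay at 0.38 and 0.34. In replicate 1 the empty vector lay at 0.00 and 0.01 on chromosome 12, and wild type at 0.15 and 0.17 on chromosome 18. Each comparison is therefore given pooled and within replicate 1 and replicates 2 and 3. The pooled main tests hold no batch term, so this difference adds to their spread, and windows that do not pass are not shown to be unchanged. Their fold changes of single genes and lists were not corrected for the shifts of whole chromosomes, so a gene can carry the shift of its chromosome. A fit without replicate 1 of a construct leaves it with replicates 2 and 3 alone, while the other constructs keep replicate 1. Construct and batch are then partly confounded, and windows that pass only in such fits do not show a construct effect. The labels do not say whether replicates 2 and 3 are separate cultures, so tests within them set the constructs against a spread near counting error and do not test a construct effect. With these replicates summed and a batch term, 89, 19 and 117 H3K4me2 windows passed for wild type against empty vector, mutant against empty vector and wild type against mutant, and 22, 1 and 19 H3K4me1 windows.

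**Figure D1:**
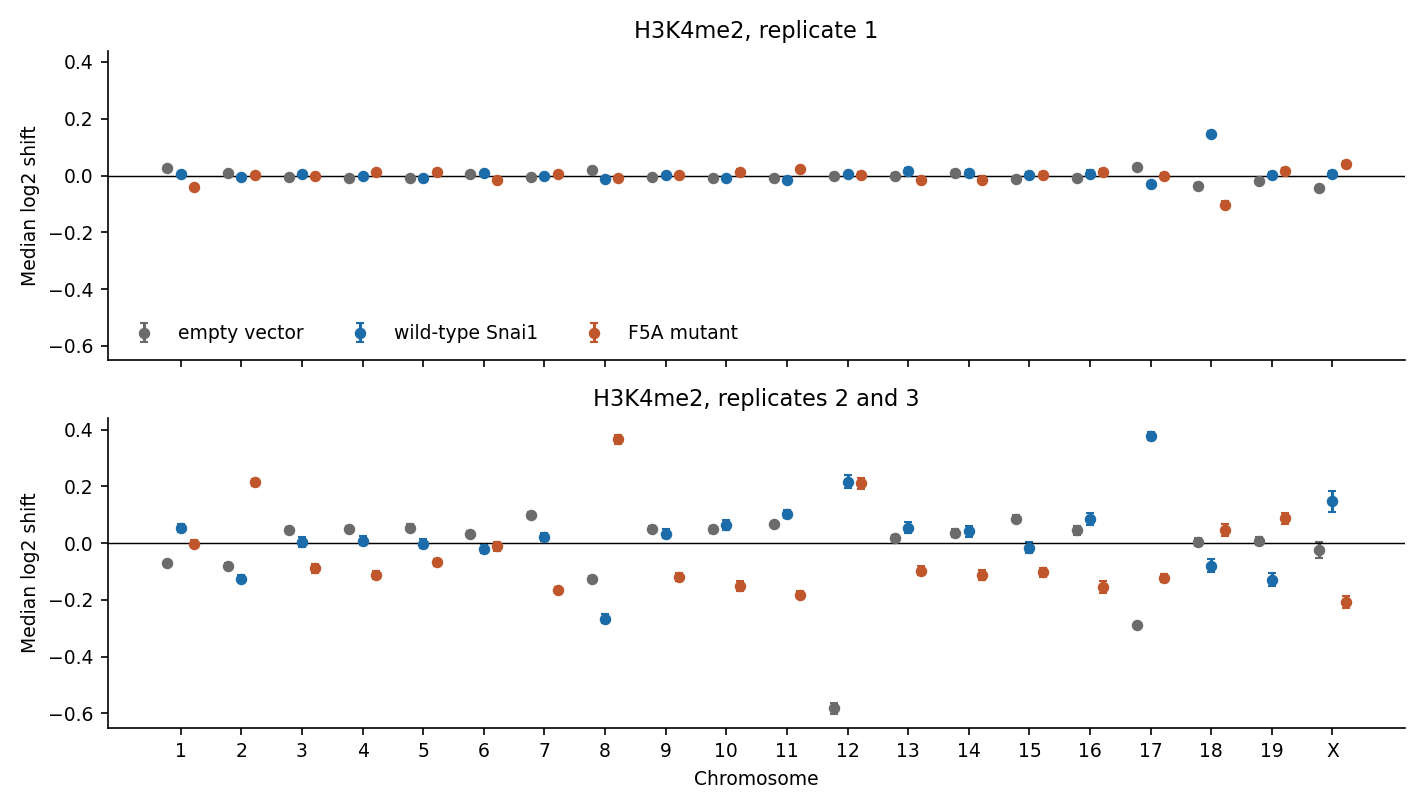
Median log2 shift of H3K4me2 windows on each chromosome (horizontal axis) in each construct against the other constructs, for replicate 1 (upper panel) and replicates 2 and 3 (lower panel), with bars of 1 standard error over windows. In the lower panel the empty vector lies at -0.58 on chromosome 12 and the mutant at 0.37 on chromosome 8.

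At the Snai1 locus (gene ID 20613 in the count table; GRCm38 chromosome 2, 167538195 to 167542814) the vector cDNA can add reads. H3K4me2 CPM over the Snai1 window was 29.7 ± 5.03 (SD, n = 3) in empty-vector, 41.2 ± 9.0 in wild-type and 40.8 ± 11.03 in mutant libraries. H3K4me1 CPM was 77.5 ± 1.70 in wild-type and 87.8 ± 14.3 in mutant libraries. With the empty vector H3K4me1 CPM was 87.46 in replicate 1 and 63.13 and 64.85 in replicates 2 and 3, which count as 1 sample. IgG gave 70.5 ± 11.1 (n = 2). The log2 fold change of Snai1 H3K4me2 against the empty vector was 0.54 (SE 0.238) for wild type and 0.47 (SE 0.237) for the mutant, and neither passed edgeR's quasi-likelihood test (adjusted p = 0.641 and 0.952). The mutant value was 0.11 without mutant replicate 1 and the wild-type value 0.34 without wild-type replicate 2. Kdm1a, which encodes Lsd1, had log2 fold changes of 0.07 and -0.02 in H3K4me2, and Gfi1b, a repressor that also recruits Lsd1, had 0.11 and 0.24. With each library left out, the Kdm1a values ran from -0.065 to 0.203 and from -0.154 to 0.05. Those of Gfi1b ran from -0.026 to 0.247 and from 0.105 to 0.353. Gfi1, its paralogue, carried 33.7 ± 14.3 CPM of H3K4me2 with the empty vector, 18 ± 2.35 with wild type and 15.6 ± 2.36 with the mutant (log2 fold changes -0.90, SE 0.293, and -1.11, SE 0.295). Neither difference passed over all windows (adjusted p = 0.497 and 0.952), and replicate 1 gave 0.19 and -0.42 where replicates 2 and 3 gave -1.30 and -1.30. Without empty-vector replicate 1, Gfi1 passed in both comparisons (adjusted p = 0.00532 and 0.00485), in a fit where construct and batch are partly confounded.

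Where Snai1 bound was asked from the deposited peak lists, which hold 137 peaks for the empty vector, 2929 for wild type and 12037 for the mutant. Among the 12 wild-type peaks with the highest -log10 q that met no empty-vector peak, the nearest genes included Disp3 (chromosome 4, 148293041 to 148293936; 60.9-fold over local background, 5298 bp beyond the gene). Others were nearest to Mir129-1 (54.8-fold, 39990 bp away), Rasa2 (chromosome 9, 96649725 to 96650312; 41.0-fold, 18418 bp away) and Nfkbil1 (33.8-fold). A further one lay inside Runx1 (chromosome 16, 92801649 to 92802300; 25.2-fold), the transcription factor gene required for blood stem cell formation. All of these places also held mutant peaks, of 32.4-, 24.2-, 20.7-, 26.1- and 11.8-fold. The strongest mutant peaks lay at Hmbox1 (chromosome 14, 64949599 to 64950247; 62.7-fold, 9.90-fold in wild type), 2540 bp from Atp13a2 (55.1-fold, 31.9-fold in wild type), at Ccdc25 (49.0-fold, 14.3-fold in wild type) and at Scamp2 (44.7-fold, 18.1-fold in wild type). Over the Snai1 gene itself there was a mutant peak of 4.83-fold (167538660 to 167538875) and no peak in the other lists.

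Wild-type peaks lay near genes of progenitor identity and of H3K4 methylation more often than near all other genes, silent ones included. Of 30 stem and progenitor genes, 8 had a wild-type peak within 5 kb of either gene end, against 7.52% of other genes (Fisher's exact test over genes, two-sided, adjusted p = 0.00959). These included the stem cell factor receptor gene Kit (chromosome 5, 75574328 to 75574822; 10.2-fold, mutant 11.1-fold), Ikzf2 (9.78-fold, mutant 8.03-fold), Lyl1 (7.72-fold, mutant 20.6-fold, 3081 bp away and inside Nfix) and Hhex (chromosome 19, 37434025 to 37434434; 8.0-fold, no mutant peak). Of 22 genes for H3K4-modifying enzymes, 7 had a wild-type peak (adjusted p = 0.00959), among them the MLL cofactor gene Men1 (13.5-fold), the demethylase gene Kdm5a (8.27-fold, mutant 38.5-fold), Rbbp5 (6.41-fold) and the methyltransferase gene Setd7 (7.72-fold). The other 10 lists did not pass for wild-type peaks. Their shares ran from 0 of 26 lymphoid and 2 of 42 myeloid genes to 15.4% of housekeeping and 16.7% of epithelial genes. Among epithelial genes, where Snai1 is a known repressor, Crb3 (14.7-fold, mutant 34.1-fold) and Cldn4 (7.92-fold, mutant 12.5-fold) were among the 5 of 30 with a wild-type peak (adjusted p = 0.286). Near mutant peaks lay 18 of 26 housekeeping genes (adjusted p = 0.000388), 17 of 30 cell cycle genes (0.00959) and 12 of 22 H3K4 enzyme genes (0.0426), against 28.1% of other genes. The other 9 lists did not pass for mutant peaks, stem and progenitor genes (12 of 30, adjusted p = 0.419) among them. In the silent families, 1 of 1482 genes had a wild-type peak nearby and 5 had a mutant peak. Windows of genes near a wild-type peak had a median log2 of H3K4me2 over IgG of 0.885, against -2.06 for all windows. The progenitor (1.27), enzyme (1.31), housekeeping (1.34) and cell cycle (1.20) lists were also high, and the last 2 did not pass for wild-type peaks. No list was compared with genes of like H3K4me2 signal, so enrichment beyond that of active genes was not tested.

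Most wild-type sites recurred in the mutant list and most mutant sites did not recur in the wild-type list. Of the wild-type peaks 2486 (84.9%, exact 95% interval 83.5 to 86.2%) overlapped a mutant peak by at least 1 base, and of the mutant peaks 2493 (20.7%, 20.0 to 21.5%) overlapped a wild-type peak. Among the 500 strongest mutant peaks 87.6% (84.4 to 90.4%) had a wild-type peak, and among ranks 8001 to 12037 it was 6.84%. Mutant peaks with a wild-type peak had a median -log10 q of 17.97 and those without one 7.46. Genes near both kinds of peak numbered 1773, where independent lists of 1900 and 7092 of 25185 genes would share 535 (odds ratio 47.2). That expectation counts all genes, among them the silent families, which had almost no peaks in either list. Each list is a pool of technical replicates, so peak numbers compare lists and have no replicate check, and the intervals cover counting error only.

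**Figure D2:**
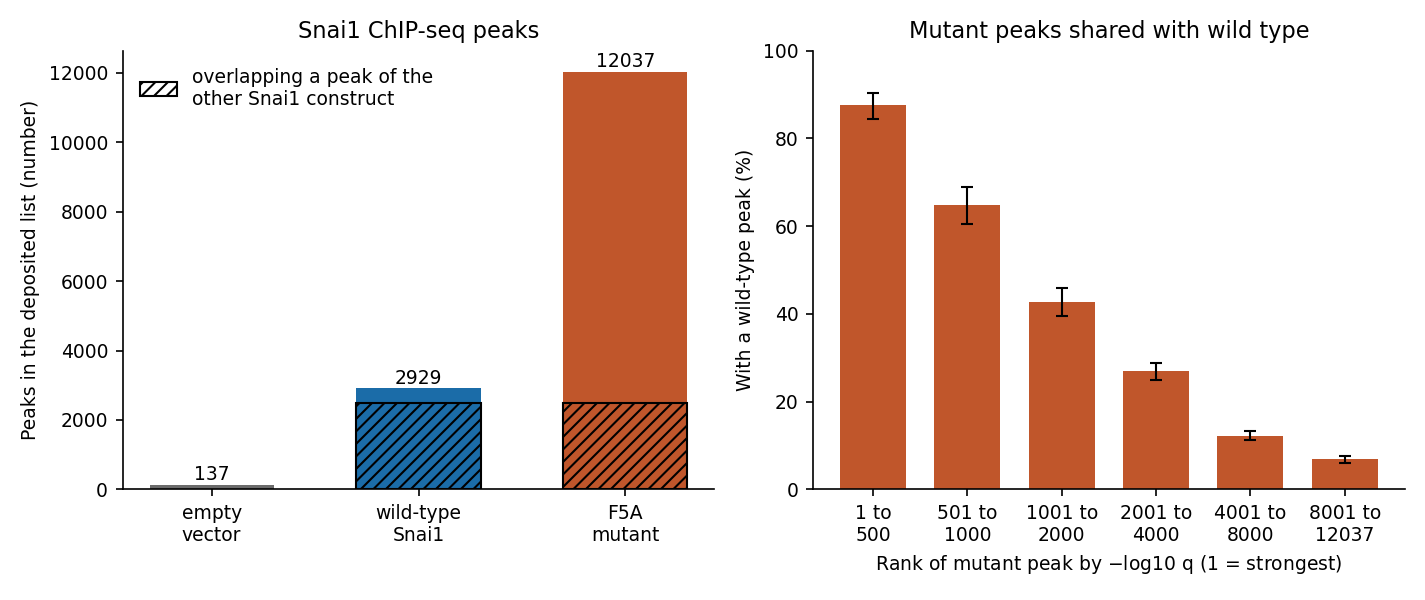
Left, number of Snai1 peaks in the deposited list of each construct, with hatching for peaks that overlap a peak of the other Snai1 construct. Right, percent of mutant peaks that overlap a wild-type peak by rank of -log10 q, with exact 95% binomial intervals, which falls from 87.6% in ranks 1 to 500 to 6.84% in ranks 8001 to 12037.

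The comparison of wild type with the empty vector asks where H3K4me2 at start sites differs when Snai1 is added. Glyat, which encodes a glycine conjugating enzyme (gene ID 107146; chromosome 19, 12633308 to 12651737), carried 50.9 ± 15.3 CPM of H3K4me2 in wild type (SD, n = 3) and 13.2 ± 0.92 with the empty vector. This log2 fold change of 1.95 (SE 0.235) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 25742 windows (adjusted p = 0.0326). The fit counts replicates 2 and 3 as separate samples, which the labels do not state, so this p-value may be too small. All 3 wild-type libraries lay above all 3 others, with log2 fold changes of 1.24 in replicate 1 and 2.22 in replicates 2 and 3. No other window passed, 1884 had an unadjusted p under 0.05, and DESeq2 called 45 higher and 50 lower. Values below the threshold with the smallest p were lower at Tom1l1 (log2 -1.29, SE 0.194; 17.6 ± 5.39 against 43.2 ± 1.80 CPM), Lrrc4b (-1.07), N4bp3 (-1.94, sharing reads with an overlapping window), Grxcr1 (-1.67), Olfr272 (-1.53), the EGF-TM7 receptor gene Adgre4 (-0.89) and the fractalkine receptor gene Cx3cr1 (-1.67), and higher at Rbpms (0.66) and Cables1 (0.81), with adjusted p from 0.139 to 0.417. Without empty-vector replicate 1 the count was 719 with all 10 of these genes passing, and without wild-type replicate 1 it was 176 with 7 of them. In both fits construct and batch are partly confounded. The count was 0 without empty-vector replicate 2 or 3 or wild-type replicate 2 or 3 (Glyat adjusted p 0.183 to 0.402, log2 1.80 to 1.96). It was also 0 with only the 6 compared libraries in the fit (smallest adjusted p = 0.557). With silent-family scaling it was 62 (22 higher, 40 lower), with the replicate number as a block 5, and with a batch term 23. Within replicates 2 and 3 alone 6063 windows passed, of which 48.2% had the same sign in replicate 1, which has 1 library per construct and no test.

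Among the fixed lists in this comparison, myeloid genes shifted down (limma's camera, adjusted p = 0.0151, and 0.626 with an estimated correlation): 31 of 42 were negative, with a median of -0.13, and 0 passed over all windows. Adjusted over the list alone 3 passed, namely Lyz2 (lysozyme; log2 -1.12, 10.5 ± 4.33 against 23.1 ± 3.13 CPM), the M-CSF receptor gene Csf1r and Id2 (0.67), an inhibitor of basic helix-loop-helix factors. None of these values was corrected for a shift of the gene's chromosome, and Id2 went against the direction of the list. Cell cycle genes shifted up (adjusted p = 0.00309, and 0.626 with an estimated correlation), with 26 of 30 positive, a median of 0.11 and 0 passing over all windows or adjusted over the list alone. Among them the inhibitor gene Cdkn1a had 202 ± 29.2 against 125 ± 29.6 CPM (log2 0.68) and Ccnd3 a log2 fold change of 0.35. Cdkn1a lies on chromosome 17. Against the other constructs, that chromosome's H3K4me2 median in replicates 2 and 3 lay at 0.376 in wild type and -0.29 with the empty vector. The myeloid and cell cycle medians were 0.04 and -0.01 in replicate 1 and -0.20 and 0.17 in replicates 2 and 3. The myeloid call was lost without empty-vector replicate 2 (adjusted p = 0.21) or 3 (0.219) or wild-type replicate 1 (0.102), and its median was -0.23 without empty-vector replicate 1. The cell cycle call held in all 6 such fits (0.000769 to 0.0424). Scaled to the silent families, which moved the median of all windows to 0.12, the medians were 0.01 for the myeloid and 0.24 for the cell cycle list, and with column totals the latter was 0.03. The other 10 lists did not pass (adjusted p 0.194 to 0.273), though with a batch term the mast cell and basophil list did (0.043). Among their members the mast cell protease gene Cpa3 had 146 ± 50.8 against 79.1 ± 39.5 CPM (log2 0.89) and the IL-33 receptor gene Il1rl1 0.68, the lymphoid gene Il7r -1.38 (the 1 lymphoid gene that passed adjusted over the list alone), and the epithelial genes Marveld3 and Krt8 -0.97 and -0.85. Without empty-vector replicate 1, 8 of the 24 named list members passed, and without wild-type replicate 1, 2 did.

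**Figure D3:**
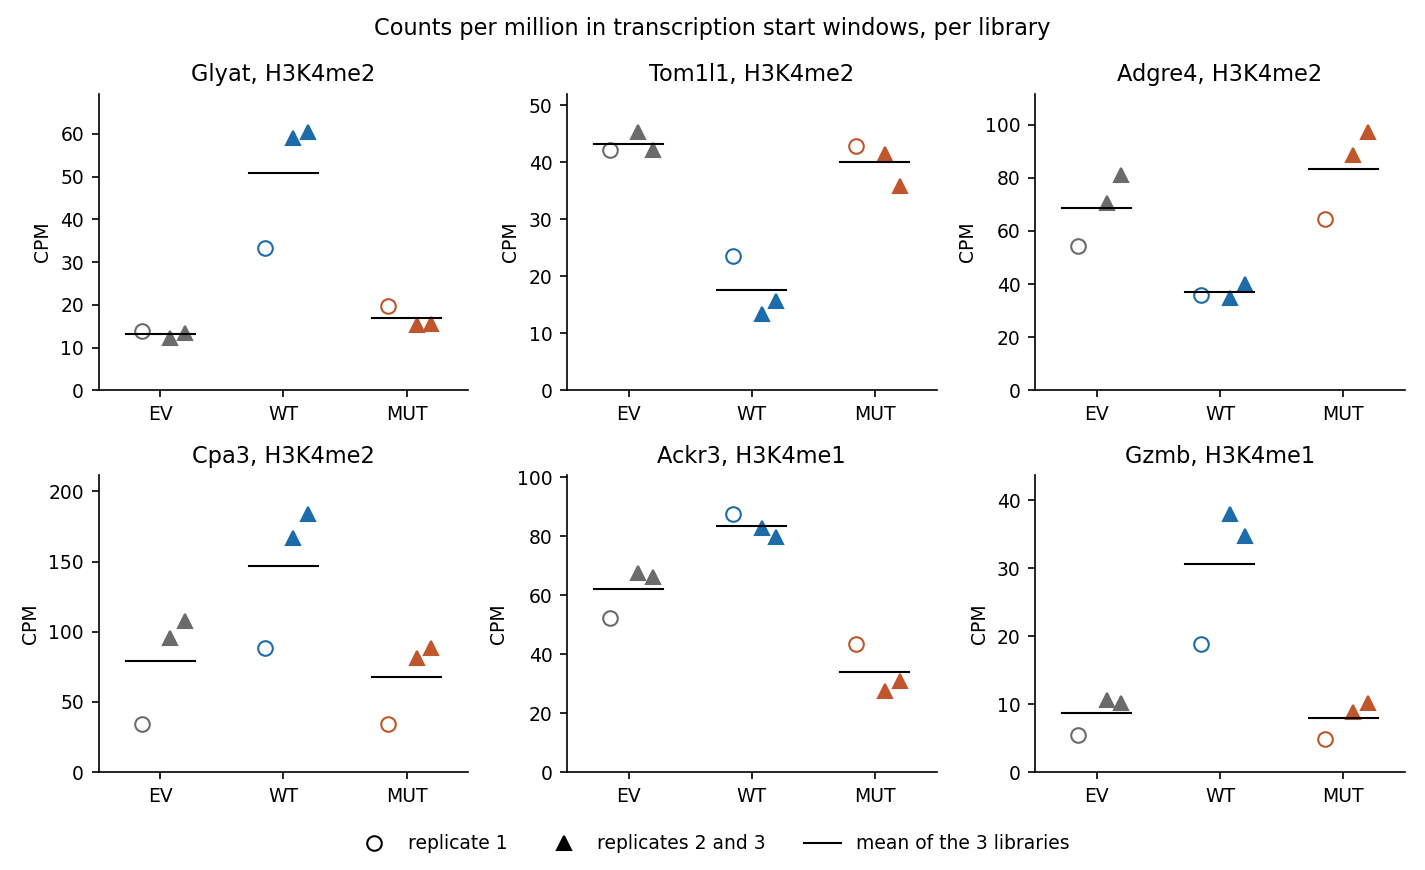
CPM (vertical axis) in the start-site windows of 6 genes in each library of the empty vector (EV), wild-type Snai1 (WT) and the mutant (MUT), with open circles for replicate 1, triangles for replicates 2 and 3 and lines for the mean of 3 libraries. Glyat H3K4me2 in WT lies above every EV library, with means of 50.9 and 13.2 CPM, and Gzmb H3K4me1 reaches a mean of 30.4 CPM in WT against 7.94 in MUT.

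The mutant was set against the empty vector to ask what H3K4me2 does when the interaction of Snai1 with Lsd1 is impaired. Genes of the erythroid and megakaryocytic list shifted up: 25 of 31 were positive with a median log2 fold change of 0.22 (camera, adjusted p = 0.000245, and adjusted p = 0.206 with an estimated correlation). Myeloid genes shifted down, with 31 of 42 negative and a median of -0.13 (adjusted p = 1.89e-06, and 0.386 with an estimated correlation). Csf1r had a log2 fold change of -0.60 and Gfi1, counted in this list and among Lsd1 partners, -1.11. Interferon response genes passed narrowly (adjusted p = 0.0496, and 0.696 with an estimated correlation; 16 of 26 negative, median -0.11, mean -0.03), with Xaf1 at -0.52 and Cxcl10 at 1.33. In these 3 lists 0 members passed over all windows and 0 adjusted over the list alone.

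None of these H3K4me2 calls of the mutant held with an estimated correlation. For the erythroid, myeloid and interferon lists medians were 0.09, 0.08 and 0.08 in replicate 1 and 0.44, -0.27 and -0.24 in replicates 2 and 3. The erythroid and myeloid calls held in each of the 6 fits without a library (adjusted p 0.000334 to 0.00195 and 1.17e-09 to 0.00122), but their medians moved. The erythroid median was 0.37 without empty-vector replicate 1 and 0.14 without empty-vector replicate 2. The myeloid and interferon medians were -0.24 and -0.18 without empty-vector replicate 1, and -0.22 and -0.21 without mutant replicate 1. Silent-family scaling moved the median of all windows to -0.13 and those of the erythroid, myeloid and interferon lists to 0.08, -0.28 and -0.23. The interferon call was lost without empty-vector replicate 2 (0.196) or 3 (0.294) or mutant replicate 1 (0.203) or 2 (0.103), and with silent-family scaling (0.288), the replicate number as a block (0.0765) or a batch term (0.0759). The other 9 lists did not pass (0.0845 to 0.629), and Gfi1 was the 1 Lsd1 complex gene that passed adjusted over the list alone.

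No window passed by edgeR's test for H3K4me2 between the mutant and the empty vector (0 of 25742, smallest adjusted p = 0.952). At an unadjusted p under 0.05 there were 1274, about the share of 0.05 that chance gives, and DESeq2 called 4 higher and 2 lower. The smallest p-values belonged to Olfr417 (log2 1.34; 54.0 ± 22.1 against 21.2 ± 3.79 CPM), the homeobox gene Evx2 (0.68), Sp9 (1.37), Aldoc (1.76), Mindy4 (2.03), Actr5 (0.50), Slc16a10 (1.30), Asic4 (0.61), Nfkb1 (0.41), a subunit of NF-kappa-B, and the adenosine receptor gene Adora2b (-0.87). The progenitor gene Lmo2 had 48.7 ± 31.2 against 16.6 ± 3.34 CPM (log2 1.55), with -0.01 in replicate 1 and 1.84 in replicates 2 and 3. Without empty-vector replicate 1 the count was 407 with 5 of the 10 lowest-p genes and 5 of 23 list members passing, and without mutant replicate 1 it was 620 with 9 and 6. It was 15 with silent-family scaling (6 higher, 9 lower). Replicates 2 and 3 alone gave 8436 passing windows, of which 31.8% had the same sign in replicate 1.

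Wild type against mutant Snai1 is the direct comparison of Snai1 with intact and with impaired Lsd1 interaction. For H3K4me2 the genes of H3K4-modifying enzymes were higher in wild type as a set (camera, adjusted p = 0.00449, and 0.537 with an estimated correlation): 19 of 22 were positive with a median of 0.13, including the demethylase genes Kdm5c (93.3 ± 8.90 against 62.2 ± 20.99 CPM; SD, n = 3) and Kdm1b (log2 0.24). Cell cycle genes were higher too, with 23 of 30 positive and a median of 0.11 (adjusted p = 0.000822, and 0.537 with an estimated correlation), including Cdkn1a (log2 0.59) and the mitotic kinase gene Aurkb (0.40). Cdkn1a lies on chromosome 17, whose median in replicates 2 and 3 lay at 0.376 in wild type and -0.123 in the mutant. Housekeeping genes followed with 17 of 26 positive and a median of 0.08 (adjusted p = 0.0354, and 0.537 with an estimated correlation), including Polr2a (0.41) and Vcp (0.24). In these lists 0 members passed over all windows or adjusted over the list alone. Replicate 1 medians were negative (-0.10, -0.12 and -0.08) and those of replicates 2 and 3 positive (0.23, 0.23 and 0.16). The ratio of housekeeping to silent-family CPM in H3K4me2 went the same way, at 49.0 in wild type and 61.1 in the mutant in replicate 1, and at 50.6 to 56.3 and 27.7 to 29.0 in replicates 2 and 3. The enzyme and cell cycle calls held in all 6 fits without a library (adjusted p 0.00038 to 0.0468 and 2.96e-05 to 0.0243), with medians that moved. Without mutant replicate 1 the medians of enzymes, cell cycle and housekeeping genes were 0.29, 0.25 and 0.20. The enzyme median was 0.06 without mutant replicate 2 and 0.08 without replicate 3, and the cell cycle median 0.17 without wild-type replicate 1. The housekeeping call was lost without mutant replicate 2 (0.05, adjusted p = 0.17) or 3 (0.04, 0.154), with silent-family scaling (0.0897) and with column totals (0.101). Silent-family scaling moved the median of all windows to 0.25 and the 3 list medians to 0.37, 0.37 and 0.33, and column totals moved them to -0.13 and to 0.06, 0.03 and -0.01.

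No window passed between wild type and mutant for H3K4me2 (0 by edgeR, smallest adjusted p = 0.124), 2548 had an unadjusted p under 0.05, and DESeq2 called 29 higher and 43 lower. Adgre4 had 37.0 ± 2.80 CPM in wild type and 83.4 ± 16.8 in the mutant (log2 -1.17, SE 0.166, adjusted p = 0.124), with -0.84 in replicate 1 and -1.31 in replicates 2 and 3. Glyat had a log2 fold change of 1.59 (SE 0.231, adjusted p = 0.124), with 0.75 and 1.94. Smim5 (-1.27), Tom1l1 (-1.18), Parm1 (-0.65), Kcnj2 (-2.27), Lrrc4b (-0.81) and the red cell membrane genes Sptb (-1.22) and Gypc (-2.83) were lower in wild type, and the death receptor family gene Tnfrsf26 was higher (1.13; 107 ± 28.0 against 48.7 ± 5.59 CPM), with adjusted p from 0.218 to 0.503. Myeloid members had positive values at Mpo, encoding myeloperoxidase (log2 0.79), and Csf2rb (0.47), and the mast cell gene Cpa3 had 1.11, while Lmo2 had -1.45. Csf2rb, Sptb and Snai3 (-0.73) passed adjusted over their lists alone, 1 in each of the myeloid, erythroid and mesenchymal lists, and 0 passed over all windows. The other 9 lists did not pass (adjusted p 0.0782 to 0.967). Without wild-type replicate 1 the count was 247 and without mutant replicate 1 it was 4289, with all 10 lowest-p genes passing in both and 2 and 19 of the 23 list members. With only the 6 compared libraries in the fit it was 2, with silent-family scaling 51 (30 higher, 21 lower), with a block 12 and with a batch term 22. Restricted to replicates 2 and 3, 15021 windows passed, of which 22.9% had the same sign in replicate 1.

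For H3K4me1, which marks enhancers and promoter flanks, wild type against the empty vector gave higher values at mast cell and basophil genes, with 16 of 20 positive and a median log2 fold change of 0.14 (camera, adjusted p = 0.0285). This call and the other 4 of this comparison were lost with an estimated correlation (adjusted p = 0.592 with an estimated correlation for the erythroid list and 0.756 for the others). Slc18a2, the vesicular monoamine transporter gene, had 117 ± 9.37 CPM in wild type (SD, n = 3) against 92.0 ± 10.8 (n = 2). Erythroid genes were higher with 19 of 31 positive and a median of 0.11 (adjusted p = 0.0466), including Car2 (log2 0.51) and the haem synthesis gene Alas2 (0.81). Cell cycle genes (24 of 30 positive, median 0.08, adjusted p = 0.0213), such as Rb1 (0.41) and Pcna (0.33), and housekeeping genes (19 of 26, 0.11, 0.0347), such as Vcp (0.30) and Tbp (0.29), were higher as well. Myeloid genes were lower with 26 of 42 negative and a median of -0.10 (adjusted p = 0.0329), including the NADPH oxidase gene Cybb (log2 -1.65) and Lyz2 (-0.90). In these 5 lists 0 members passed over all windows or adjusted over the list alone.

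Medians of these H3K4me1 lists in replicate 1 were 0.01, -0.03, -0.11, -0.11 and -0.04 for mast cell, erythroid, cell cycle, housekeeping and myeloid genes, and in replicates 2 and 3 0.26, 0.15, 0.22, 0.23 and -0.25. Without empty-vector replicate 1 the medians were 0.29, 0.195, 0.18, 0.19 and -0.18 in the same order. All 5 calls were lost without empty-vector replicates 2 and 3 (medians 0.00, 0.035, 0.04, 0.04 and -0.11, adjusted p 0.572 to 0.848, a fit in which the lone empty-vector sample is assumed to vary like the other groups). Without wild-type replicate 1 the mast cell (0.196) and erythroid (0.179) calls were lost, and the cell cycle, housekeeping and myeloid medians were 0.16, 0.195 and -0.26. Without wild-type replicate 2 the myeloid (median -0.055, adjusted p = 0.0843), erythroid (0.04, 0.15), cell cycle (0.045, 0.361) and housekeeping (0.02, 0.503) calls were lost. Without replicate 3 it was the myeloid (median -0.03, adjusted p = 0.144), erythroid (0.0602) and housekeeping (0.0621) calls. Silent-family scaling ended all 5 calls (0.091 for each), and a batch term the myeloid call (median -0.02, adjusted p = 0.0978). The other 7 lists did not pass (0.288 to 0.874), though with a batch term the stem and progenitor list did, as higher in wild type (0.00588), with medians of -0.09 in replicate 1 and 0.23 in replicates 2 and 3.

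No H3K4me1 window passed between wild type and the empty vector (0 of 25728 by edgeR, every adjusted p = 1). An unadjusted p under 0.05 was found for 742, below the share of 0.05 that chance gives, and DESeq2 called 2 higher and 2 lower. Gzmb, which encodes the cytotoxic protease granzyme B, had 30.4 ± 10.2 CPM in wild type and 7.86 ± 3.50 with the empty vector (log2 1.93, SE 0.426), with 1.75 in replicate 1 and 1.77 in replicates 2 and 3. Glyat had a log2 fold change of 1.12, Tspan8 1.02 and Mir499 1.37, and the B cell coactivator gene Pou2af1 had -1.43, Hr -0.89, Mymk -0.86, Olfr1342 -1.31, Grxcr1 -1.91 and Phgr1 -1.20. The count was 2 without wild-type replicate 1, where 0 of these genes passed, 2 with the block and 2 with a batch term, which called Gzmb (adjusted p = 0.0164). Restricted to replicates 2 and 3, 7358 windows passed, of which 37.4% had the same sign in replicate 1.

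In the mutant, erythroid and megakaryocytic genes shifted up in H3K4me1 as well: 23 of 31 were positive with a median log2 fold change of 0.27 against the empty vector (camera, adjusted p = 1.48e-06). This call held with an estimated correlation (adjusted p = 0.0217 with an estimated correlation), and fry, which tests the list without reference to other windows, gave an adjusted p of 0.085. Hbb-bs, a beta globin gene, had 13.0 ± 4.32 CPM in the mutant (SD, n = 3) against 5.35 ± 1.69 (n = 2), and the platelet tubulin gene Tubb1 76.6 ± 22.2 against 43.9 ± 1.85. The list's median was 0.22 in replicate 1 and 0.31 in replicates 2 and 3. In replicate 1 every list had a positive median (0.052 to 0.221), with 0.219 for mast cell and basophil genes. Replicate 1 therefore does not set the erythroid list apart. Myeloid genes shifted down, with 32 of 42 negative and a median of -0.15 (adjusted p = 9.4e-05, and adjusted p = 0.711 with an estimated correlation), including Cybb (log2 -0.96) and Gfi1 (-0.71). Their median was 0.19 in replicate 1 and -0.27 in replicates 2 and 3. The erythroid call was lost without empty-vector replicates 2 and 3 (median 0.15, adjusted p = 0.0835) and the myeloid call without those (-0.07, 0.109) or mutant replicate 2 (-0.04, 0.055). The myeloid median was -0.32 without mutant replicate 1 and -0.08 without replicate 3. In both lists 0 members passed over all windows or adjusted over the list alone, and the other 10 lists did not pass (0.172 to 0.974).

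No H3K4me1 window passed between the mutant and the empty vector (0 by edgeR, every adjusted p = 1). An unadjusted p under 0.05 was found for 415, below the share of 0.05 that chance gives, and DESeq2 called 0. The cytokine gene Il1b, whose window shares reads with Il1bos, had 150 ± 8.02 CPM in the mutant against 89.7 ± 15.9 (log2 0.74). Il1b lies on chromosome 2, whose median in replicates 2 and 3 lay at 0.231 in the mutant and -0.083 with the empty vector. Unc5cl (0.89), Actr5 (0.86), Tspan15 (1.21), Adam21 (1.06) and Ankrd65 (0.96) also had positive values, and the chemokine scavenger gene Ackr3 (-0.80) and the guanylate-binding protein gene Gbp10 (-1.20) negative ones. No named gene passed in any of the 5 fits without a library. Replicates 2 and 3 alone gave 6230 passing windows, of which 40.7% had the same sign in replicate 1.

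Between wild type and mutant, H3K4me1 was highest relative to the mutant at Gzmb (log2 1.95; 30.4 ± 10.2 against 7.94 ± 2.69 CPM; SD, n = 3) and Ackr3 (1.29, SE 0.192; 83.1 ± 3.89 against 33.9 ± 8.47 CPM) among the named windows. Gzmb had 1.87 in replicate 1 and 1.90 in replicates 2 and 3, and Ackr3 1.00 and 1.47. Lower values stood at Il1b (-0.89; 80.8 ± 7.28 against 150 ± 8.02 CPM), Unc5cl (-1.15), Ampd3 (-0.98), Tspo2 (-1.31), Ppp1r3d (-0.96) and the overlapping Fam217b (-0.96), and Mospd2 had 1.00. Il1b, Ppp1r3d and Fam217b lie on chromosome 2. Against the other constructs, that chromosome's median in replicates 2 and 3 lay at -0.146 in wild type and 0.231 in the mutant. In replicate 1 these genes had -0.667, -0.447 and -0.466, and in replicates 2 and 3 -1.009, -1.246 and -1.222. Of the erythroid genes Klf1, the red cell master regulator, had -0.55 and Tubb1 -0.77, and the progenitor gene Lmo2 -0.57. No window passed (0 by edgeR, smallest adjusted p = 0.63), 1347 had an unadjusted p under 0.05, and DESeq2 called 8 higher and 23 lower. None of the 12 lists passed (adjusted p 0.153 to 0.953), and 2 passed without wild-type replicate 1 and 5 without mutant replicate 1. Without mutant replicate 1 the count of windows was 211, with 9 of the 10 lowest-p genes and 1 of 24 list members passing, and without wild-type replicate 1 it was 2. It was 2 with a block and 30 with a batch term. Within replicates 2 and 3 alone 10142 windows passed, of which 29.8% had the same sign in replicate 1.

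Some gene groups passed in none of the 6 comparisons of constructs in the main tests. Median log2 fold changes of epithelial genes lay between -0.11 and 0.00 (adjusted p 0.228 to 0.874), of mesenchymal genes between -0.19 and 0.07 (0.175 to 0.926), of stem and progenitor genes between -0.04 and 0.09 (0.175 to 0.926, but 0.00588 for H3K4me1 in wild type against the empty vector with a batch term), of lymphoid genes between -0.08 and 0.04 (0.172 to 0.967), and of Lsd1 complex genes between -0.03 and 0.09 (0.0782 to 0.953). The test of whether wild-type Snai1 moved H3K4me2 and H3K4me1 differently from each other called 0 of 26008 windows by edgeR, with 157 at an unadjusted p under 0.05, and 0 by DESeq2.

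Start-site windows of genes with a wild-type Snai1 peak within 5 kb of either gene end (1897 windows for H3K4me2) asked whether methylation differed at such genes. Without window coordinates or strand, it is not known how many of these windows hold a peak. Their median H3K4me2 log2 fold change lay above that of other windows by 0.06 in wild type against the empty vector (camera, adjusted p = 0.000421) and by 0.18 in wild type against mutant (4.72e-10), and the difference was -0.08 in the mutant against the empty vector (0.000138). For H3K4me1 these differences were 0.05 (0.0154), 0.08 (0.00217) and -0.02 (0.3). None held with an estimated correlation (adjusted p = 0.744 with an estimated correlation for the 5 calls). In replicate 1 the H3K4me2 differences were -0.02, -0.10 and 0.08, opposite in sign to those of replicates 2 and 3 (0.12, 0.40 and -0.21). The ratio of housekeeping to silent-family CPM turned likewise for the mutant, which in H3K4me2 had 61.1 in replicate 1 against 48.6 with the empty vector and 49.0 in wild type, and 27.7 to 29.0 in replicates 2 and 3 against 40.9 to 42.6 and 50.6 to 56.3. Replicate 1 was also opposite for H3K4me1 (-0.08, -0.185 and 0.09 against 0.17, 0.26 and -0.07). For the mutant against the empty vector, the H3K4me2 call was lost without mutant replicate 2 (-0.02, adjusted p = 0.373) or 3 (-0.04, 0.0677), and without mutant replicate 1 the difference was -0.21. The difference between wild type and mutant was 0.33 without mutant replicate 1, 0.09 without replicate 2 and 0.11 without replicate 3. For wild type against the empty vector it was 0.12 without wild-type replicate 1 and 0.03 without replicate 2.

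In H3K4me1 single libraries decided several of these differences at windows of genes near a Snai1 peak. For wild type against the empty vector the call was lost without empty-vector replicates 2 and 3 (-0.03, adjusted p = 0.571) or wild-type replicate 2 (0.015, 0.649). It was 0.12 without empty-vector replicate 1 and 0.11 without wild-type replicate 1. For wild type against mutant it was lost without wild-type replicate 2 (0.035, 0.223) or mutant replicate 2 (0.01, 0.736) or 3 (0.03, 0.129), and it was 0.21 without mutant replicate 1 and 0.13 without wild-type replicate 1. For the mutant against the empty vector a negative difference passed without mutant replicate 1 (-0.15, 3.82e-06) or empty-vector replicates 2 and 3 (-0.10, 0.000659), and a positive one without mutant replicate 2 (0.05, 0.0157).

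The changes of wild type and mutant against their shared empty-vector libraries correlated less than simulated groups without a change. Across 25742 windows, which are not independent replicates, Pearson's r was 0.282 for H3K4me2 with a covariance of 0.0231, where 100 simulations of unchanged groups against the same controls gave 0.508 and 0.0349. For H3K4me1 r was 0.345 with a covariance of 0.0248, against 0.575 and 0.0623. Simulations that also carried the difference between replicate 1 and replicates 2 and 3 gave r of 0.512 (0.5 to 0.526) for H3K4me2 and 0.591 (0.577 to 0.606) for H3K4me1, with covariances of 0.0276 and 0.0446. Within replicate 1 r was 0.393 for H3K4me2 and 0.143 for H3K4me1, and within replicates 2 and 3 it was 0.167 and 0.351. With so few controls they could not be split into separate sets. The simulations with the batch drew each library independently around means shared by the constructs, so they held no enrichment difference between constructs. In H3K4me2 replicates 2 and 3 the ratio of housekeeping to silent-family CPM was 40.9 to 42.6 with the empty vector. It was lower in the mutant (27.7 to 29.0) and higher in wild type (50.6 to 56.3). The lower correlation therefore does not show opposing effects of the constructs.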

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

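The tests with a batch term, with replicates 2 and 3 alone or summed, with the 9 H3K4me1 libraries apart, and of the gene lists without a library were chosen after seeing the data, as was counting empty-vector H3K4me1 replicates 2 and 3 as 1 sample in the main tests, and the other alternatives given here before. Across 27 results that answer a comparison, 156 of 206 alternative values (libraries left out not counted) kept their direction, their side of the threshold or their size. For named genes and lists 2058 of 2398 did, 314 passed only under the alternative and 26 passed only in the main test. With libraries left out it was 64 of 102 and 1199 of 1330, and 1 result turned its direction. Glyat in H3K4me2 was the 1 window that passed in the main tests. A value of another gene that stayed below the threshold counted as kept even where its sign changed. An example is Kdm1a in H3K4me2 for wild type, at -0.065 without empty-vector replicate 1. The shares for named genes therefore do not measure stability of direction or size. Factors by RLE, column totals, no count filter and the libraries counted apart left every count of windows within 1.5 times. In all that follows the cause was not tested, except that replicates 2 and 3 alone lie closer together (0.980 to 2.30 times counting variance) than all 3 replicates.

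Counts of H3K4me2 windows are given for wild type against empty vector, mutant against empty vector and wild type against mutant, where the main counts are 1, 0 and 0. Silent-family factors gave 62, 15 and 51. They moved the median log2 fold change of all windows to 0.12, -0.13 and 0.25, where column totals gave -0.13 for wild type against mutant. DESeq2 gave 95, 6 and 72, a batch term 23, 0 and 22, replicates 2 and 3 only 6063, 8436 and 15021, and these replicates summed with the batch term 89, 19 and 117. With only the compared groups in the fit it was 0, 0 and 2. For H3K4me1, where the main counts are 0, DESeq2 gave 4, 0 and 31, a batch term 2, 0 and 30, replicates 2 and 3 only 7358, 6230 and 10142, and these replicates summed with the batch term 22, 1 and 19.

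With the replicate number as a block, H3K4me2 counts were 5, 0 and 12 and H3K4me1 counts 2, 0 and 2 in the same order, and the interaction of mark and construct stayed at 0. The replicate numbers were not taken to pair the samples, since not every correlation between libraries of the same number was above 0.1 (15 of 18 were, range -0.215 to 0.574). Those not above 0.1 were all between wild type and mutant (-0.067 and -0.215 in H3K4me2, -0.079 in H3K4me1), and every one against the empty vector was above it. The difference between replicate 1 and replicates 2 and 3 thus stays in the spread of the main tests. The block ended the H3K4me2 interferon call of the mutant (adjusted p = 0.0765) and no other call of a list.

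With each library left out, H3K4me2 counts ranged from 0 to 719, 0 to 620 and 0 to 4289, and H3K4me1 counts from 0 to 2, 0 to 0 and 0 to 211. The count of the interaction ranged from 0 to 0. The difference of medians at windows of genes near a Snai1 peak ranged from 0.031 to 0.119, -0.213 to -0.017 and 0.086 to 0.33 in H3K4me2. In H3K4me1 it ranged from -0.027 to 0.124, -0.15 to 0.051 and 0.005 to 0.209. The result that turned was the mutant against the empty vector in H3K4me1, at 0.047 without mutant replicate 2. Lists that passed numbered 1 to 3, 2 to 6 and 2 to 5 in H3K4me2, and 0 to 7, 1 to 5 and 0 to 5 in H3K4me1.

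With an estimated correlation the differences at windows of genes near a Snai1 peak no longer passed (adjusted p of 0.744 from camera). They were 0.062, -0.084 and 0.18 in H3K4me2, and 0.053 (wild type against empty vector) and 0.076 (wild type against mutant) in H3K4me1. Replicates 2 and 3 summed with the batch term gave 0.039 (0.0519) and 0.018 (0.253) for those H3K4me1 differences, and 0.041, -0.04 and 0.094 for the H3K4me2 differences, which still passed (adjusted p 0.0102, 0.0102 and 3.21e-06). The number of lists that passed with an estimated correlation was 0, 0 and 0 in H3K4me2 and 0, 1 and 0 in H3K4me1. It was 0 for H3K4me1 in wild type against empty vector with silent-family factors. Replicates 2 and 3 only gave 5 lists for H3K4me2 in the mutant against the empty vector and 5 for H3K4me1 in wild type against mutant.

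The share of wild-type peaks that overlap a mutant peak was 82.79% where at least 50% of the peak had to be covered, 73.78% with summits within 100 bases and 82.71% at a -log10 q of at least 5. For mutant peaks overlapping a wild-type peak the shares were 17.74% and 17.95% with the first and the second of these. The alternatives for E-box motifs were not run for want of a genome sequence, and 1 window per symbol was not run since the table has 1 row per gene ID. At these depths, spreads and sample numbers 9% of simulated 2-fold changes were recovered in H3K4me1 against 62.7% in H3K4me2. H3K4me1 windows held the higher median counts (101 to 201 against 72 to 143). Column totals ran from 4042976 to 8813537 in H3K4me1 and from 8694515 to 18199945 in H3K4me2. Whether counts per window account for the lower recovery was not tested, nor was depth apart from spread and number of samples.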

Other observations

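Chosen after the result was seen were the tests with a batch term, of agreement between batches, of H3K4me1 in the mutant for enrichment, of both explanations for the mutant peaks, of a construct effect on chromosome 12 and of copy number over all chromosomes, while the others were chosen before.

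With a batch term for replicate 1 against replicates 2 and 3, single genes of mixed kinds passed in wild-type Snai1 cells (edgeR's quasi-likelihood test). These genes were chosen after their values were seen, from the 23 and 22 H3K4me2 windows and the 2 and 30 H3K4me1 windows that passed with that term for wild type against the empty vector and against the mutant, and no theme among them was tested. Outside empty-vector H3K4me1 the fit counts replicates 2 and 3 as separate samples, which the labels do not state, so its p-values may be too small. With these replicates summed, 89 and 117 H3K4me2 windows and 22 and 19 H3K4me1 windows passed in the same order. Cpa3, the mast cell carboxypeptidase gene, was higher in H3K4me2 than with the empty vector (log2 0.98, adjusted p = 0.00481) and than in the mutant (1.16, 0.000744), with 1.38 and 1.36 in replicate 1 and 0.79 and 1.05 in replicates 2 and 3. In H3K4me1 its CPM overlapped between wild type (94.2 to 102) and the empty vector (86.9 to 102). Gzmb was higher in H3K4me1 against both (1.81, 0.0164, and 1.94, 0.00306), as was Nkg7, a granule protein gene of cytotoxic lymphocytes, in H3K4me2 against the mutant (1.17, 0.0265). Also higher than in the mutant in H3K4me2 were Tnfrsf26 (1.09, 0.00108), Tbxas1, encoding thromboxane synthase (0.91, 0.00252), the steroid enzyme gene Cyp11a1 (1.33, 0.00546), the adaptor gene Lat2 (1.01, 0.0282) and the beta chain receptor gene Csf2rb2 (0.69, 0.0282). Adgre4 (-1.14, 0.000744), Tom1l1 (-1.19, 0.00669) and the imprinted gene Dlk1 (-2.29, 0.0343) were lower. In H3K4me1, Cd40 (-1.31, 0.0409), Il1b (-0.90, 0.0409) and the red cell and platelet genes Rhd (-0.89, 0.0448) and Vwf (-0.77, 0.0448) were lower in wild type than in the mutant, and Ackr3 (1.29, 0.0229) was higher. Cd40 and Il1b lie on chromosome 2, whose H3K4me1 median in replicates 2 and 3 lay at 0.23 in the mutant and -0.15 in wild type against the other constructs. In replicate 1 that median was -0.003 in both, and the 2 genes had log2 fold changes of -0.66 and -0.67. A fit with a batch term favours genes that moved the same way in both batches, so the signs of these genes are no separate evidence, and 0 of them passed edgeR's test without the batch term, where DESeq2 gave Adgre4, Tom1l1, Tnfrsf26, Csf2rb2, Gzmb, Ackr3, Il1b and Dlk1 (the last in H3K4me1) adjusted p under 0.05 in at least 1 of these comparisons.

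Within replicates 2 and 3, up to 15021 windows separated the libraries of the constructs, which lie apart by more than replicates 2 and 3 do, though these replicates are not known to be separate cultures (summed with a batch term, 117 windows passed). A construct effect shared by both batches would make replicate 1 follow, and the correlation with replicate 1 over those windows, with the abundance trend removed, exceeded 0.1 in 0 of the 6 comparisons, which argues against it for most of these windows. Differences in enrichment over background may account for part of it: removing each library's trend with abundance left 31.4% of the H3K4me2 windows that separate wild type and mutant, but 97.3% of the H3K4me1 windows that separate the mutant and the empty vector, with 56 to 74.8% in the other 4 comparisons. Centring each chromosome left 78.2% of the H3K4me2 windows that separate wild type and the empty vector and 58.1 to 82.8% in the other comparisons, so shifts of whole chromosomes are not the whole cause in any of them. A biological difference between cultures of the constructs in that batch was not tested.

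The mutant list held 12037 Snai1 peaks against 2929 for wild type. Of the 500 strongest mutant peaks 87.6% had a wild-type partner, which leaves open whether the mutant protein bound at other sites among the weaker ones. Mutant peaks without a partner had a median -log10 q of 0.415 times that of peaks with one, but peaks found in both lists are stronger under any explanation, so this decides nothing about a deeper or more efficient immunoprecipitation in the mutant. Read depths of the Snai1 libraries are in no file at hand, and a greater amount of mutant protein or stronger binding stays open as well.

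Whole chromosomes stood apart in replicates 2 and 3, and a construct effect is argued against by replicate 1, where chromosome 12 in the empty vector lay at 0.015 in the mark with the larger shift. Copy number may differ between the cultures: IgG replicate 2 lay below replicate 1 on chromosome 8 (-0.396, SE 0.013), as wild-type H3K4me2 replicates 2 and 3 did against replicate 1 (-0.493), with the empty vector moving likewise (-0.399) and the mutant less (-0.069). The labels do not say that IgG and methylation libraries of the same replicate number share a culture. If they do, copy number does not account for all chromosomes in wild-type cells, since on chromosome 17 IgG lay at -0.254 (SE 0.014) and wild-type H3K4me2 at 0.054, while the empty vector (-0.408) and the mutant (-0.247) moved as IgG did. For chromosome 12 in the empty vector, windows at background level shifted by -0.226 (SE 0.029) in H3K4me1 and -0.327 (SE 0.027) in H3K4me2, less than the -0.46 and -0.58 of all its windows, and copy number and chromatin state cannot be told apart there because the table of window counts holds no IgG or input library of the empty vector. On the other named chromosomes background windows shifted about as far as all windows in H3K4me2 and H3K4me1, as copy number would have it, with 0.42 and 0.41 against 0.37 and 0.45 for the mutant on chromosome 8 and 0.33 and 0.29 against 0.38 and 0.34 for wild type on chromosome 17.

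Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. For H3K4me2 in wild type against the empty vector, the real split called 1 window and the highest other 0, so 1 of the 10 splits gave as many. In the mutant against the empty vector the real and the highest other split gave 0, and so did those for H3K4me1 in wild type against mutant, so all 10 splits gave as many in each. For H3K4me2 in wild type against mutant the real split gave 0 and the highest other 4, again with 10 splits as high, and that split set wild-type replicate 1 with mutant replicates 2 and 3 against the rest. It follows replicates 2 and 3, within which the 2 constructs separate 15021 windows.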
